A study of Mus musculus with 2 samples.

How the data were processed

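Polyadenylated RNA of bone-marrow-derived macrophages from C57BL/6J mice was sequenced in 1 CANDI470 sample and 1 PBS control sample, and the series' design text names paired reads of 150 bases. The deposited count tables hold whole-number counts per gene, per the file headers, with no normalization. The authors also deposited logCPM tables, whose title lines name the other sample. Their column names match the sample each was filed under, and so did the counts. Checked against the counts, the deposited log2 values were log2(count × factor + 1) with 1 factor per library for all 12726 genes in both tables, equivalent to totals, in units of 1000000 counts, of 27.4 for CANDI470 and 31.4 for the control. The method behind those factors, the aligner, the counter, the strand setting and the annotation release were not given in the sources used here. The submitters' processing notes name mm10 for both samples.

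The count tables did not share an annotation. The CANDI470 table listed 56748 gene identifiers, 19350 of them with a count, and the control listed 54532, 21361 with a count. They shared 51084, which held 99.4% of the CANDI470 counts and 99.5% of the control counts. Only 2.80% of shared identifiers had the same start and end in both tables, 94.2% had the same length and 96.4% the same symbol. Of the identifiers found in GENCODE M21, which is on GRCm38, the same start and end were given for 98.3% in the control table and 2.92% in the CANDI470 table. Coordinates are therefore printed from the control table alone, and genes were joined by identifier. Of the tested genes, 801 had lengths over 5% apart and 856 another number of overlapping genes. The gene model of Fth1, the top gene of the CANDI470 library with 2.08% of its counts, was 3469 bases long there and 866 bases in the control table. Apoe took 2.07% of the control counts, and the top 10 genes took 10.4% in CANDI470 and 12.9% in the control.

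Counts on shared identifiers were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 0.782 for CANDI470 and 1.28 for the control. Genes with at least 1 CPM in a library were kept, and the difference was log2(CPM + 1) in CANDI470 minus the control. Because each group had 1 sample, no test was run. A difference of 2-fold, and again of 4-fold, was a rule of size and not of significance. Ratio intervals are 95% exact conditional binomial (Clopper-Pearson) intervals from scipy 1.17.1 and compare these libraries, not the conditions. Their largest half-width was 0.13 on the log2 scale for the 3757 genes with at least 1000 counts in both libraries and 0.41 for the 8858 with at least 100. A count of 0 was read against a floor of 3 counts per library, 0.0927 CPM in CANDI470 and 0.0828 CPM in the control. Fold bounds from this floor are higher than the lower limits of the 95% intervals, as with 10448 against 8497 for Il6. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

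The design, the alternatives and 33 gene lists with 518 entries were fixed before the data were examined. The entries held 490 distinct genes, so some lists share members and their results are not independent. Each list's median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list stood apart when its median lay within the lowest or highest 2.5% of them. The genes named were Cxcl9 and Spp1, the 10 annotated protein-coding genes with the largest positive and the 10 with the largest negative difference, leaving out symbols made of Gm and a number or ending in Rik, and up to 4 members of each list with the largest absolute difference, plus the member farthest the other way where it differed by at least 1 on the log2 scale. Some genes that this rule names are not reported here. A few examples in the closing section were chosen after their values were seen and are given as such. Where a list held genes with 0 control counts, holding them at the floor gave medians of 7.23 for T cell chemokines, 3.74 for inflammatory cytokines, 5.14 for neutrophil and monocyte chemokines, 2.21 for mast cells and basophils, 1.66 for T and NK cells and 1.23 for fibroblasts. It left the medians of the 7 other such lists the same to 2 decimals.

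The alternatives were DESeq2 1.42.0 size factors, library totals, upper-quartile scaling, the deposited logCPM, pseudocounts of 0.1 and 5 CPM, no filter, a minimum of 5 CPM, protein-coding genes only, and random lists unmatched or matched on the control. A comparison of separate CANDI470 columns could not be run, since there was 1 column. Further alternatives were chosen after seeing the data: genes with the same model in both tables, CANDI470 counts thinned to the control depth, library totals centred on the median gene, and removal of trends in GC content and length over 20 bins of each. GC content and length came from GENCODE M21 transcripts for 99.9% of the tested genes.

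The procedure was tested on simulated Poisson counts for this comparison with 200 genes changed. All genes simulated 4-fold or 8-fold higher passed the 2-fold rule, as did 84.0% of those 4-fold lower and 95.9% of those 8-fold lower, and 0 of the unchanged genes among 12210 tested did. Such counts hold no biological or library variation. Far fewer genes were changed than differed in the data, where 3282 were at least 2-fold higher and 3013 lower. The simulation therefore does not show how well the scaling works on these libraries. The control's tables each had 3 further columns, of another control and of cultures given empty CANDI, which match neither sample and were not used here. A comparison with empty CANDI, and the spread between controls that the other control column would give, were therefore not analysed here. Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.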

Results

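Gene expression was measured by RNA sequencing of polyadenylated RNA in bone-marrow-derived macrophages of C57BL/6J mice, macrophages grown in culture from marrow precursors. CANDI470, an agent the labels give only by this code name, was added on culture day 7 at 1 mg/mL, and RNA was taken 12 h later. The control culture received PBS. Cultures given empty CANDI were not compared here, so a response that empty CANDI would also give cannot be told apart. Each group held 1 sample as used here. The CANDI470 library had 41646905 counts on genes and the PBS control library 28442450. With these samples there was no replicate check of any difference, no p-value is given, and every interval or floor covers counting error only. The libraries came in separate count tables built on different gene annotations, so the treatment cannot be told apart from the way each library was made and counted. Differences are log2(CPM + 1) in CANDI470 minus the PBS control after TMM scaling, where CPM is the count per 1000000 scaled counts. Folds on this scale understate the differences of genes with low counts.

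The series title names a macrophage state with high CXCL9 and low SPP1, so these genes were compared first. Cxcl9, which encodes a chemokine that draws activated T cells through CXCR3, had 10772 counts in CANDI470 and 1 in the control. That is 333 against 0.0276 CPM, a log2 difference of 8.34, and the CPM ratio had a 95% exact interval of 2163 to 476260. Spp1, which encodes osteopontin, had 41653 and 40150 counts, or 1287 and 1109 CPM, a log2 difference of 0.22 with a ratio interval of 1.15 to 1.18. The direction for Spp1 depended on the scaling, with -0.50 under library totals, -0.16 under upper-quartile scaling and -0.11 with trends in GC content and length removed. The counts of Cxcl9 per 1000 counts of Spp1, which need no scaling between libraries, were 259 in CANDI470 and 0.0249 in the control. In the control table, whose coordinates are those of GRCm38, Cxcl9 lies on chromosome 5 from 92321347 to 92328079 and Spp1 on chromosome 5 from 104435118 to 104441050.

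Across 12779 genes with at least 1 CPM in a library, 3282 were at least 2-fold higher in CANDI470 and 3013 at least 2-fold lower, so 52.1% of these were higher. At 4-fold, 1467 genes were higher and 941 lower. Scaling by library totals gave 2080 higher and 5152 lower (28.8% higher), and upper-quartile scaling gave 2581 and 4063 (38.8% higher). These scalings moved the median of all genes from -0.01 to -0.69 and -0.38.

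The 10 largest positive differences were led by enzymes and mediators of inflammation. Nos2, the inducible nitric oxide synthase, had 297040 counts against 4, a log2 difference of 13.01 with a ratio interval of 32462 to 305056. Acod1, which makes itaconate, was at 11.07 with 158056 against 46 counts. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was at 10.66, and Ptges, the prostaglandin E synthase, at 9.81. Inhba, which encodes the activin A subunit, was at 10.62 with 55186 against 3 counts, for which the ratio interval ran from 7045 to 99842. Arg1, the arginase that competes with Nos2 for arginine, was at 10.57 with 57356 against 6 counts, and the arginine transporter Slc7a2 was at 9.81. Il1rn, the interleukin-1 receptor antagonist, was at 10.10 with 308260 against 279 counts. The interferon-inducible GTPases Iigp1 and Gbp4 completed this set, at 9.98 and 9.80. The gene model of Iigp1 was longer in the CANDI470 table, with 5823 against 3121 bases in the control table.

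**Figure D1:**
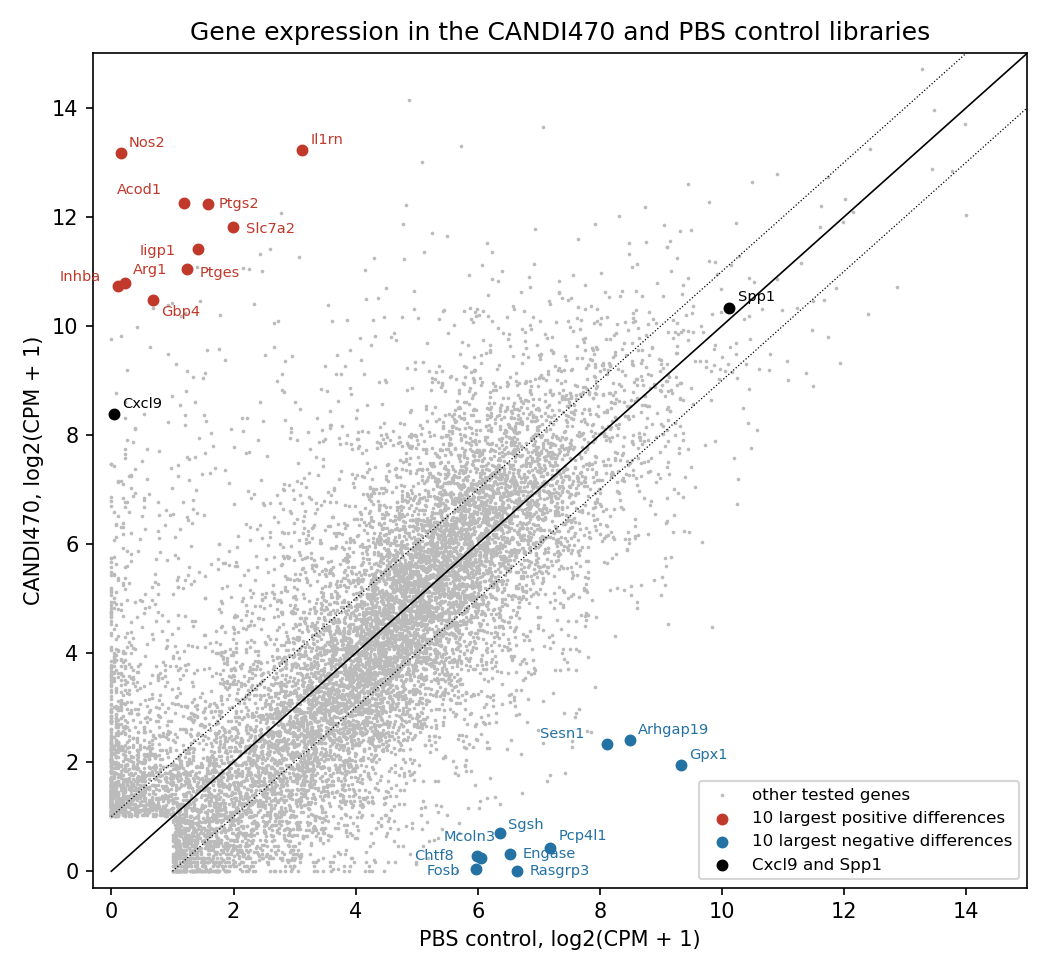
Each point is 1 of the 12779 tested genes, with log2(CPM + 1) in the PBS control on the horizontal axis and in CANDI470 on the vertical axis. The solid line marks equal values and the dotted lines a 2-fold difference. Cxcl9 lies at the left edge, with 0.0276 CPM in the control, and Spp1 lies near the line of equal values.

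The 10 largest negative differences held genes of several functions. Gpx1, the glutathione peroxidase that reduces hydrogen peroxide, had 92 counts in CANDI470 and 23265 in the control, a log2 difference of -7.39. Rasgrp3, an activator of Ras and Rap GTPases, had 0 against 3583 counts and was at least 1067-fold lower against a floor of 3 counts per library. Pcp4l1 was at -6.77, Engase, which removes N-glycans from proteins in the cytosol, at -6.20, and Arhgap19, a GTPase activating protein, at -6.08. The clamp loader factor Chtf8 was at -5.93, with 1 against 2241 counts. The ion channel gene Mcoln3 was at -5.81, the stress-response gene Sesn1 at -5.79, the AP-1 subunit Fosb at -5.70 and the lysosomal sulfamidase Sgsh at -5.67. Gpx1 and Chtf8 overlapped a further gene model in the CANDI470 table alone, and the model of Rasgrp3 had another length there.

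Interferon-induced genes were higher in CANDI470 as a group. All 25 interferon-stimulated antiviral genes were at least 2-fold higher, with a median log2 difference of 5.20, above the medians of all 10000 random lists matched on expression (percentile 100). Rsad2, the antiviral enzyme viperin, was at 9.27, Oasl1 at 8.88, Ifit2 at 7.57 and Cmpk2 at 7.40. The 20 genes of the interferon-gamma response were also all at least 2-fold higher (median 4.37, percentile 100), and beside Iigp1 and Gbp4 they included Gbp5 at 8.91 and Gbp2 at 8.18. Of 18 genes of JAK-STAT signalling and its feedback, 13 were higher and 0 lower (median 3.23, percentile 100). The feedback inhibitors Socs3 and Socs1 were at 6.84 and 5.47, the kinase Jak2 at 5.41 and Stat2 at 4.23.

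Chemokines and cytokines were higher too. Of 8 measured chemokines that recruit T cells, 7 were at least 2-fold higher (median 7.29, percentile 100): beside Cxcl9, Ccl5 was at 9.29, Cxcl10 at 8.81 and Ccl22 at 7.71. Of 12 chemokines for neutrophils and monocytes, 11 were higher (median 5.20, percentile 100), among them Ccl7 at 9.04, Ccl8 at 8.93, Ccl2 at 8.06 and Cxcl3 at 6.92. Of 19 inflammatory cytokines and mediators, 18 were higher (median 3.75, percentile 100). Il6 had 28005 counts against 0 and was at least 10448-fold higher against the floor. Of 20 genes of the NF-kB pathway and its feedback, 17 were higher and 0 lower (median 2.38, percentile 100). Tnfaip3, which restrains NF-kB signalling, was at 4.85, Traf1 at 4.82, Nfkbie at 3.35 and Tnip1 at 3.28. Among 19 Toll-like receptors and adaptors, 10 were higher and 3 lower (median 1.08, percentile 97.7), with Tlr3 at 3.31, Irak2 at 2.23, Cd14 at 1.99, Irak3 at 1.95 and Irak4 at -1.54. Its median relative to all genes was 1.09, and with a pseudocount of 0.1 or with trends in GC content and length removed it was 1.13 and 0.98, at percentiles of 97.1 and 97.0, just short of standing apart. The model of Cd14 was 1732 bases long in the CANDI470 table and 1572 in the control table.

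Genes of antigen presentation and costimulation were higher in CANDI470. Of 16 genes of costimulation and dendritic cell maturation, 13 were at least 2-fold higher and 0 lower (median 4.75, percentile 100). The migration receptor Ccr7 had 14018 against 2 counts, with a ratio interval of 2171 to 64785. Slamf1 was at 8.37, Cd200 at 7.41, and Cd274, which encodes the checkpoint ligand PD-L1, at 7.10. Of 15 genes of MHC class I presentation, 13 were higher (median 1.84, percentile 99.4), led by H2-Q7 at 4.26, the peptide transporter Tap1 at 3.31, Psme2 at 2.43 and H2-T23 at 2.37. Of 10 genes of MHC class II presentation, 7 were higher (median 1.54, percentile 98.6), with H2-Aa at 2.02, H2-Eb1 at 1.98, the invariant chain Cd74 at 1.84 and the class II transactivator Ciita at 1.73. H2-Aa, H2-Eb1 and Cd74 had longer models in the CANDI470 table than in the control table. The lengths were 3798 against 1874, 1944 against 1184 and 1679 against 1410 bases. How far this raised their differences was not tested gene by gene. Only 3 of the 10 class II genes, Ciita, Ctss and Ifi30, had the same model in both, with a median of 1.38 relative to all genes, against 1.55 for all 10, and a percentile of 85.0. H2-Q7 has near-identical copies, so its value is uncertain.

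Genes linked to SPP1-type tumour-associated macrophages were mostly higher in CANDI470, but Trem2 and Cd9 were lower and Spp1 itself was within 2-fold. Of 19 such genes, 13 were at least 2-fold higher and 2 lower (median 3.81, percentile 100). Beside Arg1, the matrix glycoprotein genes Thbs1 and Fn1 were at 6.58 and 5.72 and the membrane metalloproteinase Mmp14 at 6.49. Trem2, a lipid-sensing receptor of such macrophages, was at -3.50, with 3422 against 43842 counts, and Cd9 was at -1.96. The 4 members within 2-fold were Gpnmb at 0.81, Tgfbi at 0.36, Spp1 at 0.22 and Lgals3 at 0.21. Of 14 alternative activation genes, 10 were higher and 3 lower (median 3.56, percentile 100). Beside Arg1 and Il1rn, Chil3 was at 5.80 and Mgl2 at 5.48, while the haemoglobin scavenger receptor Cd163 was at -3.82. Of 15 metalloproteinase and matrix genes, 13 were higher and 1 lower (median 3.81, percentile 100), but this list shares members such as Mmp14 with the SPP1-type list. The collagenase Mmp13 was at 9.01 and the inhibitor Timp1 at 8.09, while Timp2 was at -2.67. Cd163 and Mmp14 overlapped a further gene model in the CANDI470 table alone, and so did Cd274 and H2-Eb1.

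Genes of resident-type macrophages were lower in CANDI470. Of 14 complement and resident-type genes, 9 were at least 2-fold lower and 3 higher, and the median of -1.78 lay below those of all random lists (percentile 0). Gas6, a bridging ligand for the clearance of dying cells, was at -5.36 with 689 against 33166 counts. Cx3cr1 was at -3.76 and Stab1 at -2.61, whereas Mertk, a receptor for Gas6, was at 2.52. Of 17 macrophage identity genes, 4 were higher and 4 lower (median -0.41, percentile 0.985). The transcription factor Cebpa was at -3.03, the growth factor receptor Csf1r at -2.24 and the Fc receptor Fcgr1 at 2.55. This list stood apart only with lists matched on mean expression, and was at percentile 17.8 unmatched and 40.5 when matched on the control. The model of Csf1r was 5774 bases long in the CANDI470 table and 4885 in the control table.

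**Figure D2:**
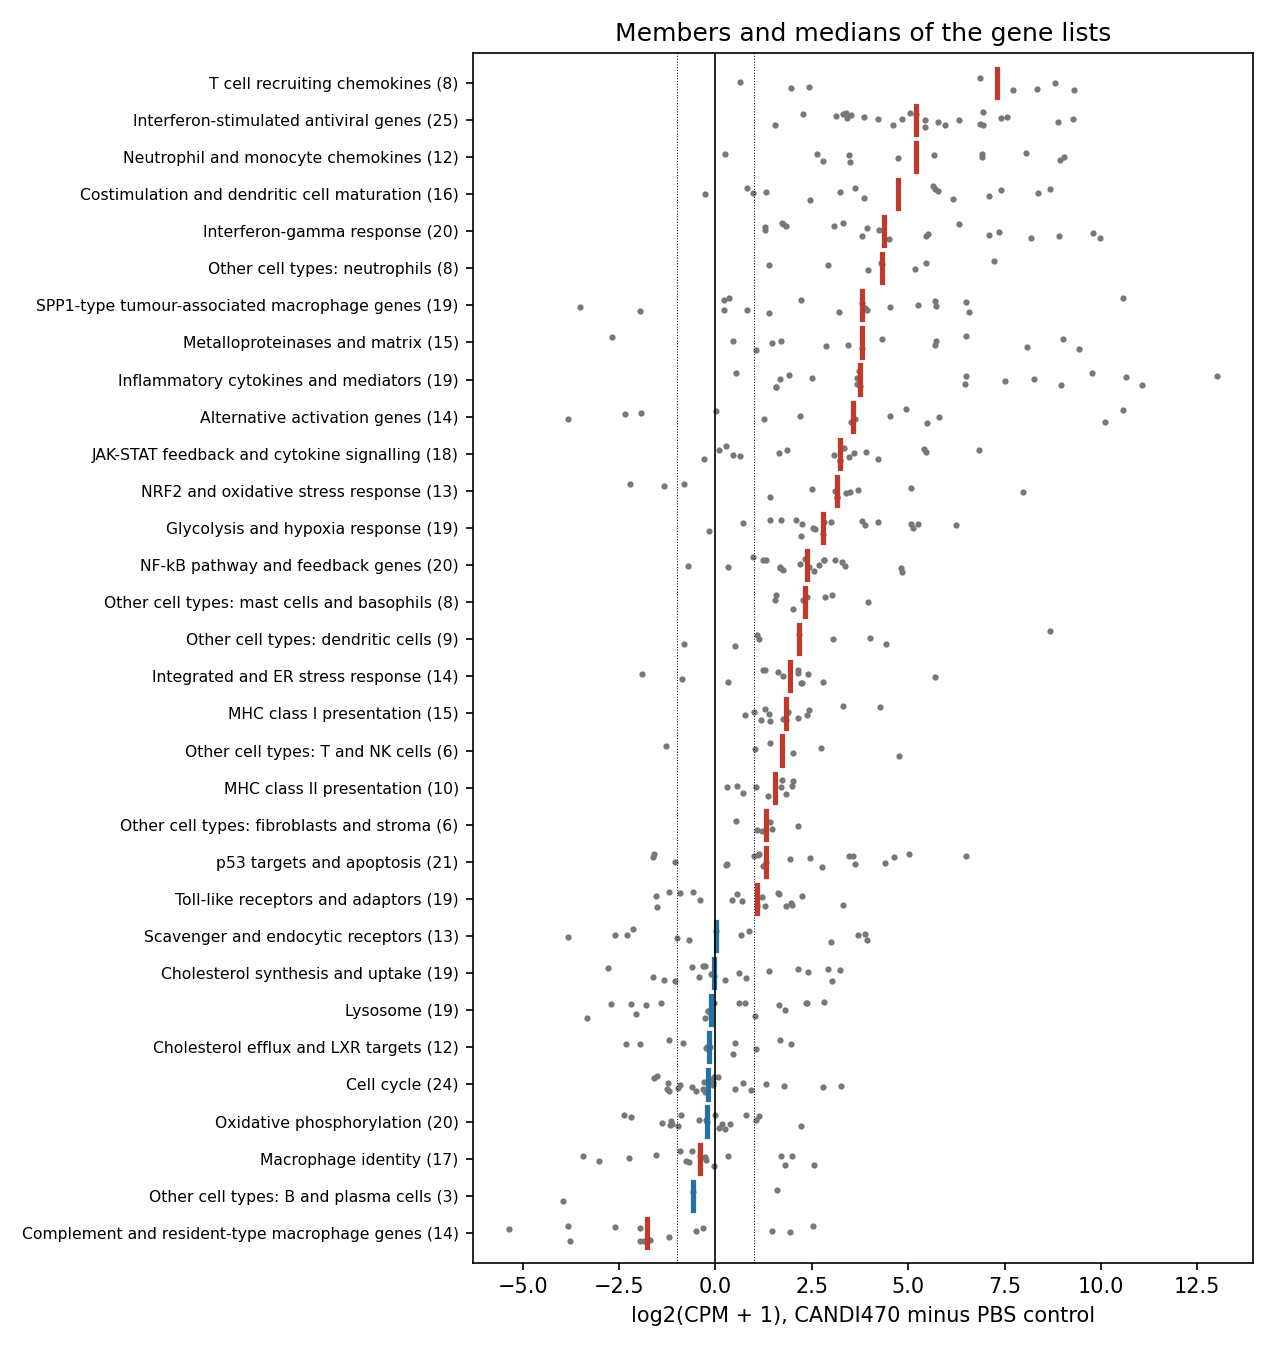
Grey points are the measured members of each gene list and vertical bars their medians, on the log2(CPM + 1) scale as CANDI470 minus the PBS control, with the number of measured members in parentheses. Red bars mark medians within the lowest or highest 2.5% of random lists and blue bars the others, and dotted lines mark a 2-fold difference. The T cell recruiting chemokines had the highest median, 7.29, and the complement and resident-type genes the lowest, -1.78.

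Metabolic and stress genes differed by pathway. Of 19 genes of glycolysis and the hypoxia response, 17 were at least 2-fold higher and 0 lower (median 2.80, percentile 100). Pfkfb3, which makes an activator of glycolysis, was at 6.23, the glucose transporter Slc2a1 at 5.25, Hif1a at 5.11 and hexokinase Hk2 at 5.08. Of 20 nuclear genes listed for oxidative phosphorylation, 3 were higher and 6 lower (median -0.23, percentile 5.52). Cycs, which encodes cytochrome c, was at 2.22, Atp5o at -2.19 and Cox4i1 at -1.39. The list also held 2 citrate cycle enzymes, Idh2 at -2.38 and Cs at 0.26. Mitochondrially encoded genes took 0.835% of the counts in CANDI470 and 2.88% in the control. Of 13 genes of the NRF2 and oxidative stress response, 10 were higher and 2 lower (median 3.15, percentile 100). The cystine transporter Slc7a11 was at 7.99, Sod2 at 5.08, Hmox1 at 3.71, Srxn1 at 3.48 and Trim16 at -2.23. Of 14 genes of the integrated and ER stress responses, 11 were higher and 1 lower (median 1.94, percentile 99.98), with Ddit4 at 5.70, Trib3 at 2.80, the chaperone Hspa5 at 2.41 and Herpud1 at -1.91. Of 21 p53 targets and apoptosis genes, 15 were higher and 3 lower (median 1.31, percentile 99.8). Mlkl, the effector of necroptosis, was at 5.02, Casp4 at 4.64, Mdm2 at 4.40 and Bax at -1.61, and Bcl2a1a, which has near-identical copies, was at 6.51.

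The lists of lipid handling, lysosome and proliferation did not stand apart from random lists. Of 19 cholesterol synthesis and uptake genes, 6 were higher and 4 lower (median -0.04, percentile 63.7). Insig1, which restrains sterol synthesis, was at 3.02 and Dhcr7 at -2.79. Of 12 genes of cholesterol efflux and LXR targets, 3 were higher and 3 lower (median -0.17, percentile 16.6), with Apoe at -1.97, Scd1 at 1.97 and Abca1 at 1.67. Of 13 scavenger receptors, 4 were higher and 5 lower (median 0.02, percentile 32.8), with Marco at 3.94, Olr1 at 3.89, Cd163 at -3.82, Fcgr2b at 3.70 and Stab1 at -2.61. Of 19 lysosomal genes, 6 were higher and 6 lower (median -0.11, percentile 4.72), with Gusb at -3.33, Ctsl at 2.81, Hexa at -2.71 and Ctsk at 2.37. Of 24 cell cycle genes, 4 were higher and 5 lower (median -0.20, percentile 62.7), with Ccne1 at 3.27, Mki67 at 2.80, Bub1 at 1.78 and Mcm6 at -1.59.

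Markers of other cell types differed as well, and their levels in CANDI470 reached 915 CPM. All 8 measured neutrophil markers were at least 2-fold higher in CANDI470 (median 4.31, percentile 100), led by Lcn2 at 7.24 with 388 CPM, Ngp at 5.46, S100a9 at 5.18 and Mmp8 at 4.32. All 8 mast cell and basophil markers were higher (median 2.32, percentile 100), with Prss34 at 3.96 on 485 against 1 counts, Cpa3 at 9.55 CPM and Mcpt8 at 7.36 CPM. Fcer1a had 135 counts against 0, at least 50.4-fold higher. Of 9 dendritic cell markers, 7 were higher (median 2.17, percentile 100), among them Ccr7 at 433 CPM, Btla at 4.43, Itgax at 4.02 and Zbtb46 at 3.04. Of 6 measured T and NK cell markers, 5 were higher and 1 lower (median 1.72, percentile 99.4). Gzmb had 843 against 0 counts, at least 315-fold higher, Il7r was at 2.74 with 915 against 136 CPM, and Cd4 at -1.29. Of 6 measured fibroblast markers, 5 were higher (median 1.31, percentile 98.4), and Thy1, Dcn and Col1a1 lay at 3.43, 1.73 and 1.76 CPM. Of 3 measured B and plasma cell markers, 1 was higher and 1 lower (median -0.57, percentile 27.7), with Igkc at 1.60 and Ighm at -3.96 on 8.59 against 148 CPM. Only 2 erythroid and megakaryocyte markers were measured, Ppbp at 3.17 and Itga2b at 1.40. Ccr7, Mmp8 and Col1a1 are each in another list as well. A marker near 0 in the control passed the 1 CPM minimum only when it was higher in CANDI470. When random lists were matched on the control, the mast cell, T and NK cell, dendritic cell and fibroblast lists, with the same medians, no longer stood apart, at percentiles 81.6, 77.9, 94.4 and 11.6.

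Differences also followed transcript composition. Across genes, which are not independent replicates, the Spearman correlation of the log2 difference was -0.26 with GC content and 0.14 with transcript length. The median difference was 0.53 in the decile of lowest GC content (median 39.4%) and -0.82 in the highest (59.2%).

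**Figure D3:**
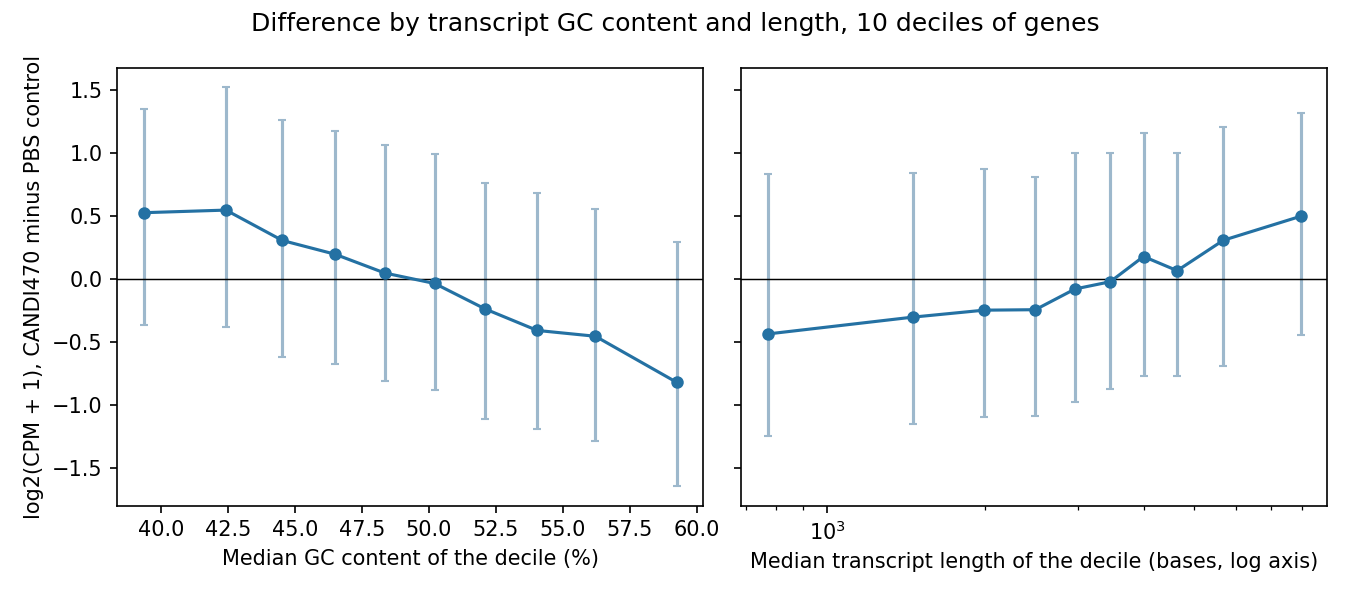
Points are the median log2(CPM + 1) differences, CANDI470 minus the PBS control, of 10 deciles of genes by transcript GC content (left) and by transcript length on a log axis (right), and bars run from the 25 to the 75 percentile. Medians run from 0.53 to -0.82 over the GC deciles and from -0.43 to 0.50 over the length deciles.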

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

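Of the tests in this part, the count of receptor genes detected, the share of lineage markers, the effect of scaling on mitochondrial genes and the comparison with nuclear genes for oxidative phosphorylation were chosen only after the results they concern were seen. The tests of GC content were written before those values were computed, but after the lowest genes had been seen.

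The ribosomal RNA gene Rn18s-rs5 took 0.474% of the CANDI470 counts, or 197577 counts, and was listed in the CANDI470 table alone, so it entered no comparison. The control table alone listed the ribosomal RNA entry CT010467.1, with 59420 counts or 0.209%. Whether both entries name the same gene was not examined.

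A set of 130 genes had at least 500 counts in the control and were at least 16-fold lower in CANDI470, Gpx1 and Rasgrp3 among them. Of these, 12.3% overlapped a further gene model in the CANDI470 table alone, against 4.81% of the other genes with as many control counts, a ratio of 2.56. That lay between the bounds of 1.5 and 3 set for the test. Overlap was judged on whole gene spans, introns included, on either strand, so it does not show shared exons. The model that Gpx1 gained lies on the opposite strand, and that of Chtf8 on the same strand. For the 16 genes concerned, lost overlapping reads may be a cause and cannot be told apart from lower expression. Of all 941 genes at least 4-fold lower, 86.9% had the same model in both tables, meaning as many overlapping genes and lengths within 5%. So did 11334 of the 12779 tested genes, so this share does not set the lower genes apart. Of the 130, 114 gained no overlapping gene model, so such gains do not account for the whole set. After subtracting the median of genes of like GC content, 100% of the 130 remained at least 4-fold lower. The 16-fold rule largely fixed that outcome in advance, since no GC decile had a median below -0.82. The typical shift with GC content was too small for these differences, but a stronger effect on single genes was not tested. Lower expression after CANDI470, such a GC effect and other differences in how the libraries were made and counted stay open for the rest.

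Markers of neutrophils, mast cells and basophils were higher in CANDI470. For reads from everywhere in the genome, the test written beforehand was the CPM ratio of olfactory and vomeronasal receptor genes, and at 8.55 it met the bound of 2 set for this cause. That ratio rested on 3 genes, with 5318 of 6160 counts on 1 of them, and was 0.678 without them. The number of receptor genes with a count, chosen after that ratio was seen, was 47 of 1994 in CANDI470 and 187 in the control. That fell on the side set against stray reads, unlike the written test. Fewer identifiers of any kind had a count in CANDI470, 19350 against 21361, and the annotations differed. The number of receptor genes detected therefore does not decide. Of 20 listed markers 80% were at least 2-fold higher (all 16 measured ones, the denominator first used). This share restates the pattern and decides nothing, since a marker near 0 in the control was measured only when higher in CANDI470. Stray reads, cells of these lineages and expression by the macrophages themselves all stay open.

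Of 13 mitochondrially encoded protein genes, 11 were at least 2-fold lower in CANDI470, with a median log2 difference of -2.36, but the most abundant, mt-Co1, was only at -0.55 with 244079 against 399288 counts, and mt-Atp8 was at 1.11 on 59 against 11 counts. Their median was -2.28 or lower under each of the 5 scalings tried, so the choice among these does not account for it. The list of nuclear genes for oxidative phosphorylation lay 2.13 above the mitochondrial genes, with or without its 2 citrate cycle enzymes, which argues against a shared lower level of respiratory transcripts. Nuclear genes in the same range of GC content had a median of 0.56, which argues against GC content, and the models of all 13 had the same length in both tables. Lower levels of most mitochondrial transcripts after CANDI470 may explain this. A difference in RNA, library preparation or counting, which the design confounds with treatment, stays open.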

How the results depend on the processing

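The settings for genes with the same model, thinned counts, centred totals and removed GC and length trends were chosen only after the results were seen. Of the 147 named genes, all but Spp1 kept their direction under every setting that gave them a value. This mostly followed from the naming rule, which picked large differences apart from Cxcl9 and Spp1. The other scalings moved the median of all genes from -0.01 to between -0.69 and 0.07 only. Values of the named genes under other settings were set against the half-width of the log2 ratio interval, which is unbounded for a gene with 0 counts. Of these, 1401 differed from the reported value by no more than that, 477 moved further and 3 turned. No filter, a minimum of 5 CPM, protein-coding genes and same models cannot change the value of a gene, and count among the 1401. Spp1 was at 0.30 with DESeq2, 0.25 with the deposited logCPM and 0.19 with centred totals, and turned to -0.50 with library totals, -0.16 with upper quartiles and -0.11 with trends removed. Cxcl9 ranged from 6.07 with a pseudocount of 5 to 11.35 with 0.1.

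Library totals gave 2080 genes at least 2-fold higher and 5152 lower, and 960 and 1857 at 4-fold, because they shift every gene down. A pseudocount of 5 gave 1774 genes 2-fold lower, and 962 higher and 408 lower at 4-fold, and one of 0.1 gave 1635 lower at 4-fold, since the pseudocount sets how far low genes can differ.

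List medians below are relative to the median of all genes. MHC class II stood at 1.38 (percentile 85.0) against 1.55 among genes with the same model, which left 3 of its 10 members. Macrophage identity stayed at -0.40, but its percentile was 17.8 with unmatched lists and 40.5 with lists matched on the control. Toll-like receptors, at 1.09 as reported, were at 1.13 (97.1) with a pseudocount of 0.1 and 0.98 (97.0) with trends removed. Lists near 0 changed sign: cholesterol synthesis to 0.070 with the deposited logCPM and 0.0018 with no filter, LXR targets to 0.32 with trends removed, scavenger receptors to -0.30 with protein-coding genes and -0.63 with trends removed, lysosome to 0.0035 with the deposited logCPM and 0.12 with trends removed, and oxidative phosphorylation to 0.0045 with trends removed. With a minimum of 5 CPM, T and NK cell markers were at 2.37 (96.6) and mast cell markers at 3.01 (92.9). Matched on the control, T and NK cells at 1.73, dendritic cells at 2.18, mast cells at 2.34 and fibroblasts at 1.33 fell to percentiles 77.9, 94.4, 81.6 and 11.6. Fibroblast markers were at 1.87 (96.5) with library totals, centred or not, 1.35 (96.8) with protein-coding genes and 1.33 (96.4) with unmatched lists. The cause was not tested for the list results. The other 454 list values kept their direction and side of the threshold. No paired analysis was possible because each group had 1 sample, and no library could be left out.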

Other observations

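The gene groups in this part were chosen only after their values were seen, and all of it is description with 1 sample per group. Their medians kept their sign under the other scalings and with GC and length trends removed. All 7 measured Schlafen genes, 11 guanylate-binding protein genes and 8 genes of the interferon-inducible Ifi200 family were at least 2-fold higher in CANDI470, with medians of 4.43, 6.32 and 5.53. Slfn4 was at 9.02 and Ifi205 at 9.44, though members of these families share similar sequences and single values are uncertain. Of 8 genes of arginine uptake and use, 7 were higher. Beside Nos2, Arg1 and Slc7a2, Ass1, which recycles citrulline towards arginine, was at 7.73, Arg2 at 5.37 and Odc1, the first enzyme of polyamine synthesis, at 3.76, while Asl was at -0.69. Of 10 genes of prostaglandin synthesis and clearance, 3 were higher and 5 lower, with a median of -0.59 that ranged from -1.26 to -0.40 over those settings. Beside Ptgs2 and Ptges, Pla2g4a, which releases arachidonic acid, was at 5.12. The synthesis genes Ptgs1, Hpgds and Tbxas1 were at -1.42, -1.32 and -1.20, and the degrading enzyme Hpgd at -4.92. Slco2b1, an organic anion transporter that is not specific to prostaglandins, was at -4.70.

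Of 12 immediate early genes, 8 were at least 2-fold lower in CANDI470 and 1 higher, with a median of -2.40. Egr1 had 158 against 8303 counts, a log2 difference of -5.29, and Fos was at -3.65. Of 10 transcription factors examined, 4 were lower (4 to 7 over those settings) and 2 higher, with Pparg at -4.68 and Mef2c at -4.13, the latter overlapping a further gene model in the CANDI470 table. Of 76 cytosolic ribosomal protein genes, 38 were at least 2-fold lower and 0 higher, with a median of -0.99. This count depended on the setting, since the median lay near the 2-fold bound: the other scalings and the removal of GC and length trends gave 25 to 67 genes and medians from -1.70 to -0.77. These genes are short and have many processed copies, so their values are uncertain where tables were counted on different annotations.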
